A study of Mus musculus with 4 samples.

How the data were processed

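Whole-genome bisulfite sequencing was done on 4 libraries of primary mouse pancreatic ductal epithelial cells on a C57BL/6 background. In bisulfite sequencing unmethylated cytosines are read as thymine and methylated cytosines stay cytosine, so that each read over a CpG gives 1 methylated or unmethylated call. According to the labels, 2 independent cell lines came from mice that carry the activated allele KRAS G12D (group K). Another 2 came from mice with the same allele that also lack both copies of LKB1 (group KL), the kinase that the gene Stk11 encodes. Each library is 1 cell line, and the lines of a genotype were the replicates. Their replicate numbers follow the order of deposition and pair nothing. Per the labels' protocols, 200 ng of DNA was sheared by sonication and converted with a bisulfite kit before a library kit for single-stranded converted DNA (Accel-NGS Methyl-Seq) added the adapters.

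The reads were aligned by the authors with BSMAP to the mouse build mm9, per the submitters' processing notes; the version is not given in the sources used here. Each of the 4 deposited files lists the CpGs read in 1 library, with the count of all read calls and the count of methylated read calls, and the deposited fraction methylated is the second count over the first. The fraction matched the counts within 0.0006 in all rows. The deposited counts are given for both strands together and for each strand. The deposited file names point to removal of duplicate reads, but no label or header describes that step or a filter on depth. Depths of over 10000 read calls occur, so that any removal left such sites in. All coordinates below are 1-based positions in mm9.

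Methylation levels were computed from the deposited counts as methylated calls over all calls. The global level used autosomal CpGs with at least 5 reads in every library. The classes low (under 20%), intermediate and high (over 80%) used CpGs with at least 10 reads in every library. CpG density was the number of CpGs per 1 kb tile, taken from the CpG positions in the files, and levels by density used CpGs with at least 1 read in every library. Groups were compared by a two-sided exact permutation test of the library values. With 2 libraries against 2 there are 6 label assignments, and the smallest p is 0.333, so no comparison of single values could pass 0.05.

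Differential methylation was tested with edgeR 4.0.16 (quasi-likelihood test, glmQLFit and glmQLFTest with package defaults, in R 4.3.3) on methylated and unmethylated read calls, with the design of modelMatrixMeth, which gives each library a term for its depth. The common dispersion came from a seeded subset of 20000 tiles. Tiles of 1 kb needed at least 3 CpGs and 20 read calls in every library. Bins of 100 kb needed at least 100 CpGs and 1000 read calls. P-values were adjusted by the Benjamini-Hochberg method, and a tile or bin was called at an adjusted p below 0.05. The regions named in the text were fixed by a rule before the data were examined: runs of at least 2 adjacent tiles called in the same direction, with both KL levels outside both K levels, the 10 with the highest and the 10 with the lowest difference. Regions on autosomes alone were added after the data were seen. Each CpG with at least 10 reads in every library was also compared between each of the 6 pairs of libraries by Fisher's exact test. Read depth per 1 Mb bin was set over each library's autosomal median, with CpGs of over 100 reads left out.

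The fits were tested on simulated data made with the real depths and the spread between libraries of a genotype. A single value of that spread was used for all tiles or for all bins, and the deepest were left out. Changes were placed only where the pooled level was in the middle of the range. In 100000 simulated 1 kb tiles of which 200 were changed, edgeR recovered 4 of 50 tiles changed by 20 percentage points, 15 of 50 changed by 30 points, 45 of 50 changed by 40 points and 46 of 50 changed by 45 points, and called 7 unchanged tiles. In 24003 simulated 100 kb bins it recovered 0 of 50 changed by 4 points, 3 of 50 changed by 6 points, 8 of 50 changed by 8 points and 44 of 50 changed by 12 points, and called 4 unchanged bins. With limma 3.58.1 on logit levels, 0, 0, 27 and 40 of the tiles of these sizes were recovered.

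Alternatives fixed before the data were examined were other read minimums, per-CpG weighting of the global level and of the densities, each library's own CpGs, X included, other tile and bin sizes, limma on logit levels with 1 added to each count, a trended dispersion, Fisher's exact test on summed reads, thinning to the shallowest library, a minimum of 10 percentage points, bins of similar depth and leaving out each library in turn. Other alternatives were chosen after seeing the data: a cap of 100 reads per CpG, per-CpG weighting of single regions and of the global level over CpGs of at least 1 read, leaving out 1 Mb bins rich in sequence variants, leaving out tiles with a depth excess in 1 genotype, and a newer quasi-likelihood estimator. A bin was called variant-rich where the share of CpGs with at least 10 reads that were read on 1 strand only was at least 2 times the library's autosomal median, on the assumption that a base change in a CpG can remove the calls of 1 strand. Repeated sequence was traced from the files alone, as arrangements of 5 neighbouring CpGs with identical spacing and flanking bases.

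Promoters, gene bodies and gene lists had been planned but were not tested, since no annotation of mm9 was used here. Regions are given by position, without gene names. The autosomal read calls per library ranged from 213510578 to 257597939, with a median of 8 to 10 reads per CpG. The edgeR and limma p-values rest on the spread between cell lines, which includes any differences between the lines that are unrelated to LKB1. For 1 kb tiles edgeR took most of that spread from all tiles together (22.99 prior degrees of freedom). A tile can therefore be called although the lines of a genotype differ widely in it. The p-values of Fisher's exact test measure only the sampling of reads.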

Results

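CpG methylation was measured genome-wide in 4 cell lines of mouse pancreatic ductal epithelium, the cells that line the pancreatic ducts. Of these, 2 lines carried the activated KRAS allele G12D alone (K) and 2 carried it with loss of LKB1 (KL). LKB1 is a kinase, encoded by Stk11, that activates AMPK and related kinases that restrain growth. The title of the series links loss of LKB1 to serine metabolism and DNA methylation, and the comparison asks how the methylome differs when LKB1 is lost beside active KRAS. Autosomal read calls at CpGs numbered 238846551 in K replicate 1, 213510578 in K replicate 2, 227112600 in KL replicate 1 and 257597939 in KL replicate 2. The median CpG was covered by 9, 8, 9 and 10 reads in these libraries, and 13333607 autosomal CpGs had at least 5 reads in every library. On the mitochondrial chromosome, where little CpG methylation is found, 0.172% and 0.154% of calls were methylated in K and 0.176% and 0.174% in KL.

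The 2 genotypes differed in sex chromosome content. X depth relative to the autosomes was 0.902 and 1.04 in the K libraries and 0.588 and 0.596 in the KL libraries. Read calls on Y numbered 40726 and 37612 in K and 247283 and 313539 in KL. Both K lines therefore had the X depth of a genome with a pair of X chromosomes, and both KL lines that of a genome with a single X and a Y. Autosomes and X are reported separately for this reason.

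Stk11 lies on chromosome 10, and its exons could not be placed because no annotation of mm9 was used here. On that chromosome 8 runs of 10 or more CpGs had no read in either KL library although both K libraries were read there, and 7 of them lay in variant-rich bins, defined by CpGs read on 1 strand only. The other ran over 18 CpGs from position 79587921 to 79588993 and held 156 and 109 read calls in the K libraries and 0 in each KL library, where a count of 0 allows up to 3 calls. At the next 7 CpGs, from 79589011 to 79589667, KL replicate 1 held at most 1 call per CpG and KL replicate 2 held 0, against 2 to 7 in K, and reads resumed at 79589808 with 10 and 14 calls in KL. The 60 CpGs before it, from 79582128 to 79587863, held 472 and 567 calls in KL against 500 and 416 in K. The 60 CpGs after it, from 79589011 to 79592929 and with these 7 among them, held 360 and 415 calls in KL against 334 and 297 in K. The stretch was singled out after the data were seen, as the 1 gap of 21 found in both KL libraries that did not lie in a variant-rich bin. No such gap of 10 or more CpGs was found in both K libraries.

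**Figure D1:**
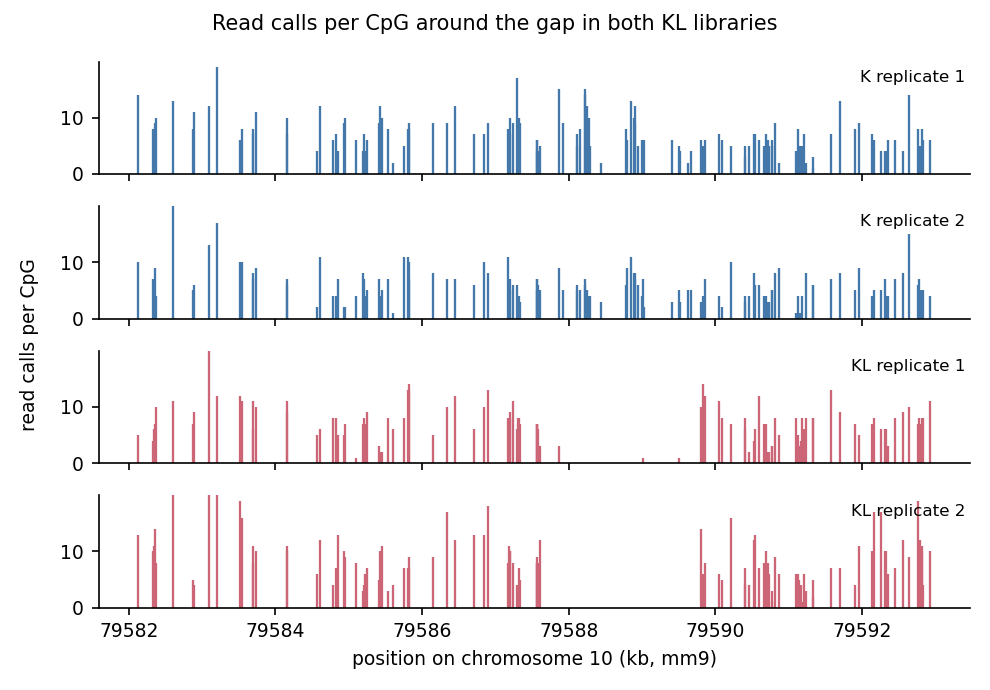
Read calls per CpG (vertical axis) against position on chromosome 10 in kb of mm9 (horizontal axis), 1 panel per library. The 18 CpGs from 79587921 to 79588993 held 156 and 109 calls in K and 0 in both KL libraries, and reads in KL resumed at 79589808.

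Autosomal methylation was higher in the KL lines. The level over CpGs with at least 5 reads in every library was 44.5% ± 1.07 (SD, n = 2) in K and 47.7% ± 0.653 (SD, n = 2) in KL, a difference of 3.16 percentage points. Both KL lines, at 48.1% and 47.2%, lay above both K lines, at 43.7% and 45.3%. Over CpGs of at most 100 reads, a cap chosen after seeing the data, the level was 39.2% ± 1.42 in K and 42.7% ± 0.692 in KL (SD, n = 2 each), a difference of 3.51 points. The uncapped levels are higher in large part because 414 CpGs with at least 10000 reads in every library, methylated at 68.6% to 71.2%, held 14.4% to 15.2% of all autosomal calls. Under the cap the order held on each of the 19 autosomes, with differences from 2.19 to 4.69 points. The exact two-sided permutation test gave p = 0.333, the smallest that 2 lines against 2 allow.

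The difference lay in CpG-poor sequence and had the opposite sign in the CpG-densest tiles. Density classes used CpGs with at least 1 read in every library, a lower minimum than the global level. In tiles with 1 to 4 CpGs per kb the level was 37.3% ± 1.11 in K and 42.2% ± 1.61 in KL (SD, n = 2 each), and in tiles with 5 to 9 CpGs it was 43.9% ± 1.48 and 48.8% ± 0.768. The difference was 3.09 points with 10 to 19 CpGs and 1.15 points with 20 to 39. In tiles with 40 or more CpGs per kb, a density typical of CpG islands, the level was 10.2% ± 0.552 in K and 9.15% ± 0.447 in KL. With at least 5 reads the levels were lower, at 34.6% and 39.5% with 1 to 4 CpGs and 7.52% and 6.64% with 40 or more. In each of the 5 classes both KL values lay on the same side of both K values, with p = 0.333 by the exact permutation test. With 20 to 39 CpGs this did not hold with each CpG weighted equally (0.772 points, exact permutation p = 0.667) or, chosen after seeing the data, over CpGs of at most 100 reads (0.878 points, exact permutation p = 0.667). Without K replicate 1 the difference was 0.707 points in that class and -0.699 in the densest, against 1.15 and -1.09 with all lines. Of the CpGs with at least 10 reads in every library, 57.1% ± 2.87 were low in K and 49.7% ± 0.691 in KL, while the intermediate class held 36.5% ± 2.40 and 43.0% ± 0.753 and the high class 6.37% ± 0.463 and 7.23% ± 0.0619 (SD, n = 2 each, exact permutation p = 0.333 for each class). The size of these shifts depended on the reads required: with at least 5 reads KL minus K was -4.76 points for low, 3.30 for intermediate and 1.47 for high, and with at least 20 reads -4.87, 3.38 and 1.497, against -7.40, 6.54 and 0.859 with at least 10. The shares themselves moved further. With at least 5 reads 33.0% of CpGs in K and 28.3% in KL were low. The intermediate class then held 45.8% and 49.1% and the high class 21.2% and 22.7%, so the shares describe the deeper CpGs only. The high class differed by 1.40 points without K replicate 2.

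**Figure D2:**
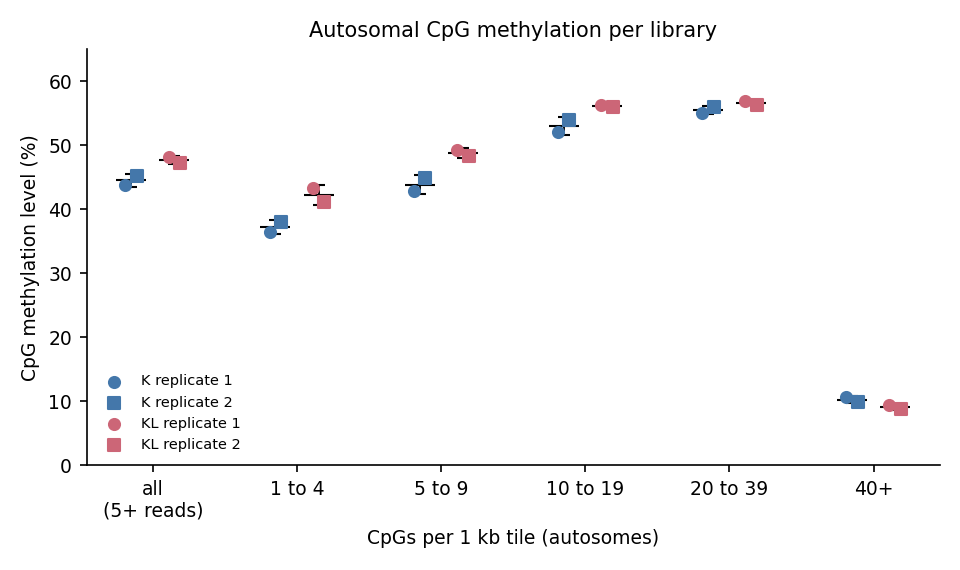
CpG methylation level in percent (vertical axis) of each library over all autosomal CpGs with at least 5 reads and over CpGs with at least 1 read in every library, grouped by the number of CpGs per 1 kb tile (horizontal axis). Symbols are libraries, and dashes with bars are means ± SD of 2 libraries. KL lies above K over all CpGs, at 47.7% against 44.5%, and below K in the densest class, at 9.15% against 10.2%.

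Broad domains followed the same direction. Of 25647 bins of 100 kb tested, 7376 were called, and on the autosomes 5822 bins were higher in KL and 129 lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05). Called bins that rose did so by a median of 7.31 points, with median levels of 35.1% in K and 43.6% in KL, while the median difference of all autosomal bins tested was 3.43 points, and 20410 of the 24011 autosomal bins had a positive difference. Of 5 equal groups of autosomal bins ordered by mean level, the least methylated, with levels up to 34.9%, held 2102 bins that rose, or 43.8% of that group, and the most methylated, above 55.9%, held 407, or 8.47%. In the groups between them, in order of level, 28.88%, 22.62% and 17.49% of bins were called higher. The mean difference was 4.09 points in the least methylated group, 4.055, 4.003 and 3.545 in those between, and 1.95 in the most methylated. Among the less methylated groups the share called higher thus fell with little change in the mean difference. On X, where K and KL also differed in copy number, 1401 bins were higher and 24 lower. Leaving out K replicate 1 gave 4583 called bins (3410 autosomal higher, 288 lower), leaving out KL replicate 1 gave 4164 (2929 higher, 142 lower) and leaving out KL replicate 2 gave 4799 (3322 higher, 75 lower). The numbers for autosomal bins were 5324 higher and 65 lower outside variant-rich bins and 5102 higher and 82 lower among bins of similar depth in all lines.

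At the scale of 1 kb, 2039 autosomal tiles were higher in KL and 1549 lower among 2033218 tested (edgeR quasi-likelihood test, adjusted p below 0.05). Higher tiles had a median of 9 CpGs and rose by a median of 32.8 points, with median levels of 22.8% in K and 61.2% in KL, while the median difference of all autosomal tiles tested was 3.64 points. Lower tiles had a median of 15 CpGs and median levels of 62.3% in K and 24.1% in KL. The direction differed with CpG density. Among tiles with 5 to 9 CpGs, 937 rose and 305 fell, while among tiles with 40 or more CpGs 15 rose and 180 fell. In 33.2% of the autosomal tiles tested both KL levels lay above both K levels and in 9.53% below. A random order of the lines, drawn separately in each tile, would give 16.7% each. All tiles share the same 4 lines, so a difference between lines over the whole genome moves them together, and these shares are no test against chance. The calls depended on the lines and the tool: the autosomal counts were 3334 higher and 2610 lower without K replicate 1, 1027 and 946 without K replicate 2, 72 and 106 without KL replicate 1, and 12 and 42 without KL replicate 2. Tiles of 500 bp gave 401 higher and 808 lower and tiles of 5 kb 15007 and 1827, so that the balance turned with tile size. With limma on logit levels 0 tiles were called, autosomal or X, with 241538 at an unadjusted p below 0.05 against 261006 with edgeR.

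The lower tiles stood apart from the higher ones in read depth and position. Both KL libraries had at least 1.5 times the relative depth of both K libraries in 333 of the 1549 lower tiles, or 21.5%, in 3 of the 2039 higher tiles and in 0.211% of the tiles not called. The reverse, at least 1.5 times the depth in both K libraries, held in 52 of the higher tiles, 17 of the lower and 5481 of the 2029630 not called. This reverse excess was thus also more frequent among the called tiles, higher ones included, than among those not called. The median depth ratio of KL over K was 0.862 in higher tiles, 1.34 in lower tiles and 1.001 in those not called. Bins of 1 Mb that were variant-rich in both KL libraries and in neither K library held 377 lower and 166 higher tiles among 72356, so that 69.4% of the called tiles there were lower. In bins that were not variant-rich, 971 were lower and 1755 higher, and 35.6% were lower. Outside variant-rich bins of every combination and without a depth excess in either genotype lay 703 of the tiles called lower and 1716 of those called higher, and a fit without all such bins and tiles, chosen after seeing the data, called 643 autosomal tiles lower and 1504 higher.

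X behaved differently from the autosomes. On X 1842 tiles were higher in KL, with median levels of 41.6% in K and 84.8% in KL, and 611 were lower. The lower X tiles were CpG-dense, with a median of 42 CpGs, and their median level was 13.1% in K and 1.35% in KL. Among X tiles with 40 or more CpGs, 35.9% were called lower, against 0.808% of such tiles on the autosomes. The difference in X copy number between K and KL goes with genotype in all 4 lines, and the X counts were 469 higher and 404 lower without K replicate 2, 3 and 72 without KL replicate 1, and 2 and 15 without KL replicate 2.

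**Figure D3:**
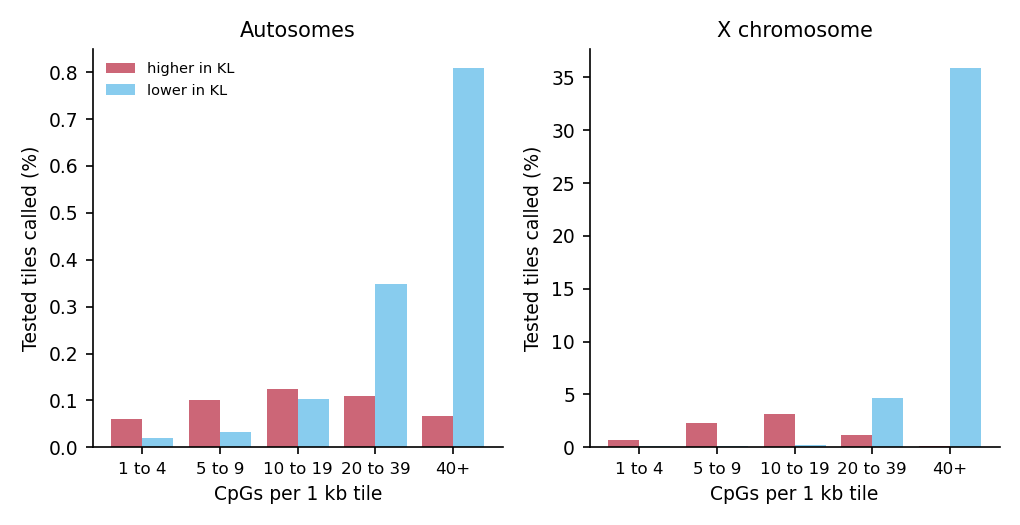
Share of tested 1 kb tiles called higher or lower in KL, in percent (vertical axis, scaled separately for autosomes and X), by the number of CpGs per tile (horizontal axis). On both, lower tiles prevail at 20 to 39 and at 40 or more CpGs. With 40 or more, 0.808% of autosomal and 35.9% of X tiles were called lower.

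Higher tiles were concentrated on chromosome 17. Between positions 8712001 and 9494000, 172 tiles were called higher and 0 lower, which was 8.44% of all autosomal tiles called higher. The called tiles of the block had median levels of 26.7% in K and 65.1% in KL. The 1 Mb bin from 8000001 to 9000000 had a level of 37.1% ± 1.07 in K and 45.3% ± 0.546 in KL, and the next, from 9000001 to 10000000, had 29.9% ± 0.298 and 41.5% ± 2.22 (SD, n = 2 each). Neither bin was variant-rich, and relative depth in the second bin was 1.18 and 1.22 in K and 1.14 and 1.098 in KL. Further bins with many higher tiles were on chromosome 7 from 121000001 to 122000000, with 35 higher and 1 lower, chromosome 6 from 87000001 to 88000000, with 32 higher and 0 lower, and chromosome 1 from 39000001 to 40000000, with 31 higher and 1 lower. The bins with the most lower tiles were on chromosome 10 from 93000001 to 94000000, with 30 lower and 4 higher, and chromosome 1 from 114000001 to 115000000, with 27 lower and 0 higher, and both were variant-rich. The next, on chromosome 4 from 102000001 to 103000000, had 25 lower and 1 higher and was not variant-rich. It held the longest run of lower tiles, 10 from 102244001 to 102254000, and relative depth there was 0.987 and 1.38 in K and 1.056 and 1.049 in KL. Its level as a whole was higher in KL, at 50.5% ± 0.136 against 47.6% ± 0.723 in K (SD, n = 2 each). Then came chromosome 10 from 92000001 to 93000000, with 22 lower and 4 higher, and chromosome 4 from 140000001 to 141000000, with 20 lower and 5 higher, both variant-rich. The bins were ranked after the data were seen.

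Runs of adjacent tiles gave 141 autosomal regions that were higher in KL and 108 that were lower. Among the 10 regions with the highest differences, 9 lay on X and 1 on chromosome 19. On X the difference in copy number goes with genotype, so the X regions cannot be assigned to LKB1 loss. The X region from 72979001 to 72981000 had levels of 22.7% ± 6.52 in K and 87.2% ± 5.52 in KL. The region on chromosome 19, from 5405001 to 5408000, held 61 CpGs and rose from 11.2% ± 1.57 to 63.9% ± 1.67 (SD, n = 2 each; adjusted p of its 3 tiles at most 0.0011 by edgeR). The other X regions began at 65952001, 147516001, 155994001, 47919001, 47944001, 47894001, 49469001 and 47973001, and rose by 50.4 to 55.05 points, and 4 of the 9 X regions thus began between 47894001 and 47973001.

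Among autosomal regions alone, the 10 highest differences ranged from 44.1 to 52.7 points. On chromosome 6 the region from 16309001 to 16311000 went from 31.0% ± 16.7 to 80.1% ± 3.51. On chromosome 17, 3 of the 10 lay in the block above, and that from 8835001 to 8839000 went from 23.1% ± 8.71 to 71.1% ± 3.73. On chromosome 2 the region from 154179001 to 154181000 held 56 CpGs and went from 32.1% ± 0.911 to 76.2% ± 3.21, with 449 and 488 read calls in KL and 502 and 525 in K. On chromosome 7, from 121566001 to 121568000, the level went from 36.6% ± 0.0481 to 82.4% ± 2.16 (SD, n = 2 each). The others began at 9013001 and 9133001 on chromosome 17, 109012001 on chromosome 12, 91936001 on chromosome 10 and 103010001 on chromosome 9.

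The 10 regions with the lowest differences were all autosomal. In 7 of them both KL libraries held over 1.5 times the read calls of both K libraries, and in 4 of these over 5 times. The lowest was on chromosome 17 from 29825001 to 29827000, at 82.8% ± 4.16 in K with 243 and 217 calls and 18.2% ± 0.577 in KL with 4634 and 5873 calls. On chromosome 2, 6 tiles from 27353001 to 27359000 went from 70.9% ± 3.68 with 870 and 901 calls to 17.8% ± 0.609 with 19995 and 27152 calls. The others of this kind began at 143037001 on chromosome 1 and 28774001 on chromosome 3. With each CpG weighted equally, chosen after seeing the data, the difference was -25.5 points in the region on chromosome 17 and -22.2 points in that on chromosome 3, against -64.5 and -45.6 over summed calls. Read calls were more alike on chromosome 11 from 8553001 to 8555000, with 245 and 196 in K and 250 and 342 in KL, where the level was 78.8% ± 4.04 in K and 29.2% ± 7.86 in KL. On chromosome 1 from 114641001 to 114643000, in a variant-rich bin, it was 74.0% ± 1.01 and 19.97% ± 6.22 (SD, n = 2 each). The remaining regions began at 124094001 on chromosome 8, 144570001 on chromosome 4 and 92702001 on chromosome 10, where both KL libraries held at least 1.93, 1.56 and 1.51 times the read calls of both K libraries, and at 115823001 on chromosome 2, with at least 1.38 times, and 4 of the 10 lay in variant-rich bins.

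**Figure D4:**
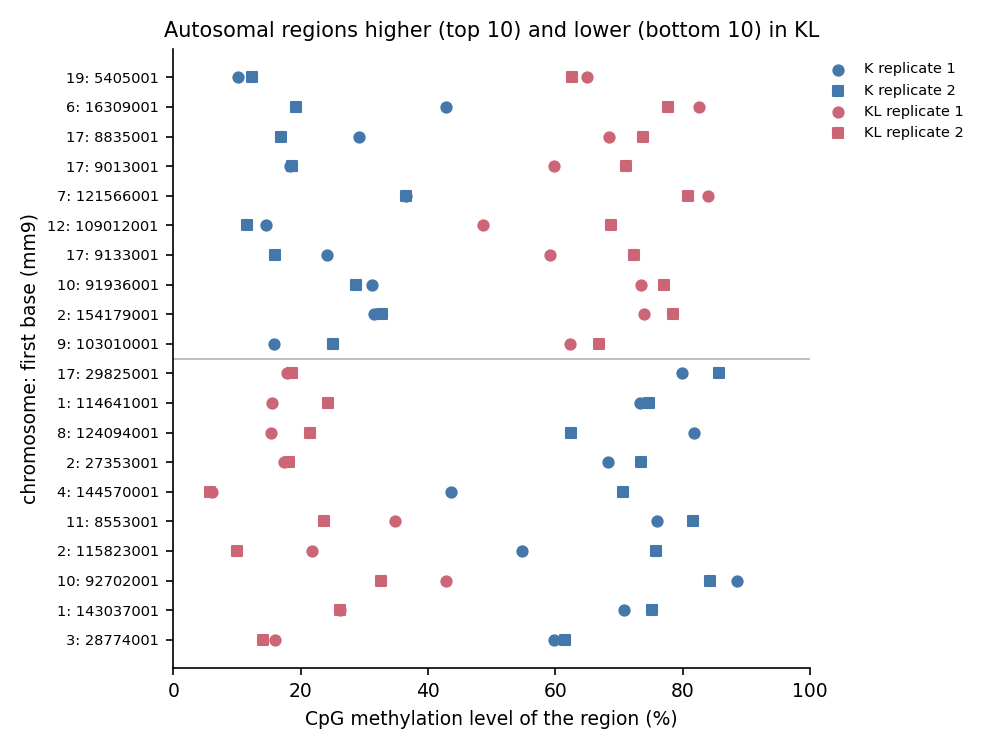
CpG methylation level in percent (horizontal axis) of each library in the 10 autosomal regions with the highest and the 10 with the lowest difference between KL and K (vertical axis, chromosome and first base in mm9). Symbols are libraries. In each region both KL values lie on 1 side of both K values.

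Single CpGs differed between libraries of a genotype as well as across genotypes. Of 3630901 autosomal CpGs with at least 10 reads in every library, 3336 differed between the K lines and 390 between the KL lines (Fisher's exact test, two-sided, Benjamini-Hochberg adjusted p below 0.05, which compares libraries and not genotypes). Across genotypes the 4 pairs gave 1988 to 6175 CpGs. K replicate 2 thus differed from KL replicate 1 at fewer CpGs, 1988, than from K replicate 1. Likewise K replicate 1 differed from KL replicate 1 at 2243 CpGs, fewer than from K replicate 2. The counts depended on depth: with libraries thinned to the shallowest, 1983 CpGs differed between the K lines, 296 between the KL lines and 1342 to 2836 across genotypes. Of the CpGs that differed without thinning, 71.5% and 72.0% were higher in the KL library in the pairs with K replicate 1, and 53.1% and 57.7% in those with K replicate 2. With at least 5 reads the shares were 50.98% and 57.2% with K replicate 1, and 42.7% and 48.2% with K replicate 2, where most CpGs that differed were then lower in KL. With at least 20 reads they were 90.6% and 92.5%, and 79.6% and 82%, over 110560 CpGs.

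Read depth showed copy number differences within the K group and few between the genotypes. Over 2413 autosomal bins of 1 Mb, the SD of the log2 depth ratio was 0.17 between the K lines, 0.05 between the KL lines and 0.11 for KL over K. The last is a ratio of means of 2 libraries, which narrows its spread, so it cannot be set directly against the ratios of single libraries. K replicate 1 had a relative depth of 1.38 over chromosome 13. K replicate 2 had 0.740 over chromosome 4, with 1.35 over the 25 bins of 1 Mb from 80 Mb onward. KL replicate 2 had 1.12 over chromosome 15. Both KL libraries differed from both K libraries by at least 1.2 fold in 5 bins.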

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

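All tests of explanations in this part were chosen after the results they address had been seen.

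The comparisons of the report leave out Y, and Y gave a signal there: read calls on Y per autosomal read call were 6.65 times as frequent in KL as in K. The second signal comes from the counts per strand, which no comparison of levels used. In 102 autosomal 1 Mb bins, both KL libraries had at least 2 times their median share of CpGs read on 1 strand only, against 15 bins shared by both K libraries. The third comes from CpGs without reads, since 21 runs of 10 or more CpGs were unread in both KL libraries and read in both K libraries, and 20 of these lay in variant-rich bins.

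Of the called autosomal tiles, only those lower in KL were set against technical explanations, of which there are 2. Reads of further copies placed on these tiles may account for part of them, since both KL libraries had at least 1.5 times the depth of both K libraries in 21.5% of the lower tiles, against 0.211% of the tiles not called. Where the excess was at least 5 times, in 93 tiles forming 65 runs on 17 chromosomes, the median relative depth of KL replicate 2 over KL replicate 1 was 1.14, with quartiles of 1.09 and 1.19, which covers the ratio of 1.12 on Y and not 1; copies on parts of Y that mm9 lacks are a candidate source for these tiles, 69 of which were called lower. In the 669 tiles with an excess of at least 2 times, of which 215 were called lower, the median was 1.089. Its quartiles of 1 and 1.17 hold 1.12 and reach down to 1, so the ratio does not separate the sources there. In all 4615 tiles with an excess of at least 1.5 times, of which 333 were called lower, the median was 1.015, with quartiles of 0.944 and 1.105. These cover 1 and not 1.12, so the source of the smaller excesses is open. Segments of another strain are a candidate source for another part: tiles called lower were 9.45 times as frequent in bins variant-rich in both KL libraries alone as in bins that were not variant-rich, against 2.30 times for tiles called higher, so that the excess was not confined to lower tiles, and it was not tested whether a variant base was misread there or whether the other allele carries less methylation. Outside variant-rich bins of every combination and without a depth excess of 1.5 times in either genotype lay 703 lower tiles. For these an effect of LKB1 loss, the sex of the animals and differences between individual lines all stay open. Depth excesses below 1.5 times were not left out of them.

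The X pattern is the second. A further X in the K lines, inactivated and methylated at its CpG islands, may account for the lower X tiles, since 35.9% of X tiles with 40 or more CpGs were called lower against 0.808% on autosomes, and X depth in KL was 0.610 times that in K. The share of 35.9% should lie near the autosomal share if neither X copy number nor LKB1 loss acted on X, and no line separates these 2. Pooled levels differed little: over CpGs of at least 5 and at most 100 reads in X tiles of that density, they were 31.3% in K and 30.3% in KL. That difference was -1.01 points, against -0.853 on autosomes. An effect of LKB1 loss on X stays open, as the X copy number goes with genotype in all 4 lines. For the same reason the 1842 X tiles called higher cannot be assigned to LKB1 loss or to X copy number. Their median levels were 41.6% in K and 84.8% in KL, and the explanation by a further X was not set against them.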

How the results depend on the processing

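The levels kept their direction in all 65 alternative values over 9 results (global, 3 classes and 5 densities), where the permutation test cannot reach 0.05, but not always their size (classes, and tiles with 20 or more CpGs), and with 20 to 39 CpGs the lines overlapped in 2 alternatives. With all 4 lines K and KL did not overlap in any of the 9 results, so leaving out a line could hardly reverse them. The global difference was 2.35 to 3.87 points with 1 line left out, 3.51 with CpGs of at most 100 reads and 3.22 outside variant-rich bins, the last 2 chosen after seeing the data. The counts of calls moved far more. With 1 line left out, and the lone line assumed to vary like the other group, 71 to 8089 tiles were called, 12 to 3334 autosomal tiles higher and 42 to 2610 lower, so that the higher tiles did not always prevail. With limma on logit levels 0 tiles were called, 0 higher and 0 lower (241538 at an unadjusted p below 0.05). In the simulation limma recovered 0 of 50 tiles changed by 30 points, near the median of the called autosomal tiles, but 27 of 50 changed by 40. The simulation held 100000 tiles against 2117034 tested, with a single spread and changes only at levels in the middle of the range. It therefore cannot explain the lack of any call. At least 50 read calls gave 2812 tiles, 1073 autosomal higher and 970 lower, over fewer tiles tested. Tiles of 5 kb gave 26148, with 15007 autosomal higher and 1827 lower. Tiles of 500 bp gave 1864, with 401 higher and 808 lower, the opposite balance, and the cause was not tested. Fisher's exact test on summed reads, which has no spread between lines, gave 253927, with 189187 higher and 39359 lower. Among alternatives chosen after seeing the data, 960 autosomal tiles were lower outside variant-rich bins, and 643 with tiles of a depth excess left out as well. With 1 line left out, 4164 to 7872 bins of 100 kb were called, 2929 to 6710 autosomal higher and 75 to 288 lower. Bins of 10 kb gave 25816, with 17165 higher and 1253 lower, over more bins. Autosomal bins called lower numbered 82 among bins of similar depth and, chosen after seeing the data, 65 outside variant-rich bins. CpGs called between library pairs averaged 4061 across genotypes and 1863 within; at least 20 reads gave 823.5 and 393.5, over fewer CpGs, and thinning gave 1917 and 1140. At least 5 reads turned the prevailing direction in both pairs with K replicate 2, to 42.7% and 48.2% higher in KL, and at least 20 reads gave 79.6% and 82%. The SD of log2 depth was 0.09 in bins of 5 Mb. The 34 regions kept their direction in all 204 alternative values, of which 14 moved by more than the spread, all with each CpG weighted equally, chosen after seeing the data. Regions were named only where both KL levels lay outside both K levels, so leaving out a line could not reverse them. Those values are therefore no test of direction, and thinning drew on the same reads. No paired analysis was possible because the labels give no replicate numbers shared by the genotypes. Promoters, gene bodies and gene lists, with their alternatives, were not run for want of an mm9 annotation. Depth of 8 to 10 reads per CpG limits single CpGs, and 2 lines per genotype limit every test.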

Other observations

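The tests in this part were chosen after the data were seen, except the read depth and the pairs of libraries.

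Over all densities, the difference between KL and K was larger at arrangements of 5 CpGs with several copies than at those with 1 copy. This contrast was not tested. Only identical arrangements were counted as copies, so a copy of a repeat whose arrangement had changed was counted as another arrangement. Arrangements with 1 copy may therefore include repeats and cannot be taken as single-copy sequence. Arrangements of 5 CpGs that occurred once in the autosomal files had a level of 39.4% ± 1.44 in K and 42.6% ± 0.581 in KL (SD, n = 2 each), over 11039253 CpGs of at most 100 reads, a difference of 3.26 points. Arrangements with 20 to 99 copies differed by 4.27 points, those with at least 100 but under 500 copies by 4.48 points and those with 500 or more copies by 4.82 points, at 45.8% ± 1.327 in K and 50.6% ± 0.756 in KL. The difference was larger with 500 or more copies than with 1 copy at each density up to 39 CpGs per kb: 6.075 against 5.11 points with 1 to 4 CpGs, 5.43 against 4.88 with 5 to 9, 5.08 against 3.52 with 10 to 19 and 3.64 against 0.509 with 20 to 39. With at least 100 but under 500 copies it was 5.03, 5.15, 5.00 and 4.09 points in these classes. With 1 to 4 CpGs per kb the order thus did not hold below 500 copies, where the difference was 4.56 points with 2 to 19 copies and 4.96 with 20 to 99, less than with 1 copy. Of 334 arrangements with at least 500 copies and 100 of them read, 261 had both KL levels above both K levels and 13 had both below, with a median difference of 4.38 points. The families of repeats were not identified, as no repeat annotation of mm9 was used here, and copies of 1 family are not independent.

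The difference also varied with the bases beside the CpG, which was not tested either. Over CpGs of at most 100 reads it was 4.81 points at TCGA and 4.20 points at ACGA, and 1.17 points at GCGC and 1.56 points at CCGC. CpG density, with which the difference varied as well, was not held constant across these contexts, so the 2 cannot be told apart here. Reads stacked on a few sites carried a smaller difference: at the 414 CpGs with at least 10000 reads in every library, of which 353 lay on chromosome 9, the level was 69.2% ± 0.755 in K and 71.0% ± 0.404 in KL.

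The higher autosomal methylation in KL was weighed against 3 explanations. Incomplete conversion of the KL libraries is argued against by the mitochondrial chromosome, where KL minus K was 0.0121 percentage points against an autosomal difference of 3.16, and by the CpG-densest tiles, where the level was lower in KL. Segments of another strain are argued against as the whole source, since the difference outside variant-rich bins was 3.22 points. The sex of the animals cannot be told apart from the genotype, because 0 of the genotypes held lines that differed in sex chromosome content. An effect of LKB1 loss is a candidate explanation that these lines leave open beside sex and differences between individual lines.

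Whether chance grouped the lines this way could not be put to a test that reaches 0.05, because 4 libraries allow only 3 splits. The real split called 6041 tiles of 1 kb and the highest other split 4, and it called 7376 bins of 100 kb and the highest other split 0, with 161 and 60 bins at an unadjusted p below 0.05 in the other splits (edgeR). In each case 1 of the 3 splits, the real one, gave a count as large. The real split is also the split by X copy number, and on X it called 1842 tiles higher and 611 lower, and 1401 bins higher and 24 lower. Each other split sets a K line beside a KL line in both groups, so any difference between K and KL lines widens its spread. The few calls of the other splits therefore do not decide whether chance grouped the lines.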
